A study of Oryza sativa Japonica Group with 10 samples.

How the data were processed

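Gene expression was measured with Affymetrix rice arrays in one-week-old rice seedlings of the japonica cultivar Zhonghua 10. Per the labels, seedlings grew with sufficient phosphate or were exposed to low phosphate for 6, 24, 48 or 72 h, and each of the 5 groups has 2 arrays called biological replicates, 10 arrays in all. Total RNA came from separate treated and nontreated plants by TRIzol extraction, and 8 µg per array was made into biotin-labelled cRNA, per the labels' protocols. How many seedlings went into a sample, and when the control was harvested, is not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

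The deposited values are signal intensities on a linear scale, 1 per probe set and array. Per the submitters' processing notes, the authors used GCOS and MAS5, and the versions are not given in the sources used here. The mean after trimming 2% at each end was 500.1 on all 10 arrays, so each array had been scaled to one target before deposit. Detection calls and scanner files were not used here. A MAS5 signal takes each array on its own, and at low signals its log2 value is noisy, so large changes of dim probe sets have wide errors. The number of arrays sets the precision of every value.

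Of the 57381 probe sets, 123 were Affymetrix controls. Among the other 57258, the platform annotation lists 1 gene for 22436, several for 95 and none for 34727, and no gene was named from a probe set with several. The 22436 probe sets stand for 17905 genes, all found in a RefSeq gene table of 39387 genes, and 2452 of them have a published symbol or synonym there. The table gives no coordinates that could be set beside the array's design, so none are printed.

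Signals were taken to log2 with no offset and the authors' scaling was kept. Probe sets were tested when their mean log2 signal over the 10 arrays was above the 40th percentile (4.579), which left 34355. limma 3.58.1 in R 4.3.3 fitted group means to all 10 arrays, which leaves 5 residual degrees of freedom, with eBayes and an intensity trend (6.5 prior degrees of freedom). The 4 low-phosphate times were each compared with the control, 72 h was compared with 6 h, and an F-test covered all 5 groups. Tests were two-sided, p was adjusted with Benjamini-Hochberg over the probe sets of a comparison, and adjusted p under 0.05 counted as a change. The rule in the series text, a ratio of group means beyond 2-fold in either direction, was applied beside it. The labels say that RNA came from independent treated and nontreated plants and call the samples of a group biological replicates. The p-values rest on the spread between 2 arrays per group.

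Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean) and at least 5 genes, and adjusted over 125 tests of 25 lists and 5 comparisons. Camera made 38 calls, 0 of which passed with an estimated correlation, and all 38 passed with fry, which tests whether a list's genes move one way on balance. Of 31 lists fixed, 30 had measured members and the list of acid phosphatases had no matched member, so it was not tested here. The annotation used here has no gene descriptions, so the lists were applied through gene symbols and synonyms. These were written down before any value other than the control probe sets was tested. Genes without a matched symbol or a tested probe set are not among the measured members, so results can cover only part of a list as fixed. Lists can share genes, and a shared gene counts in each. The housekeeping gene UBQ5 was left out because its chromosome differed between the list as fixed and the gene table.

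Named genes were taken by a rule. For each comparison they are the 8 largest rises and 8 largest falls (5 and 5 for 72 h against 6 h) among probe sets with adjusted p under 0.05, exactly 1 gene, a named gene, and both arrays of one group above both of the other, with 1 probe set per gene. The rule asked for a description of the gene product, which was read as a published symbol or synonym. All measured members of the core phosphate-starvation markers, SPX-domain proteins, phosphate transporters and phosphate-response regulators were added, and up to 4 members with the largest change in the direction of each other list that passed camera. OsLHY at 24 h, the clock genes given at 6 or 72 h, and OsCASP1, Lsi1 and Lsi2 at 6 or 24 h were chosen after their values were seen. So were the members given for lists without a camera call. A gene's other probe sets were compared with the named one. After the values were seen, changes with both arrays of the dimmer group under a signal of 23.9 were given as bounds, the brighter group's mean log2 signal less that level. The level is that of the filter and not a measured background.

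The groups, comparisons, tests, lists, the rule for named genes and the alternative settings were fixed before the data were examined. The alternatives were no filter or one at the 60th percentile, quantile normalization, median centring, an offset of 32, eBayes without a trend or robust, the replicate number as a block, only the 2 groups compared, each array left out in turn, stricter forms of the 2-fold rule, and other list tests. Fits without the 6 h or 72 h arrays, and counts with 1 probe set per gene, were added after the data had been seen. The 3′ over 5′ log2 ratios come from the Affymetrix control probe sets, with those under a mean control signal of 100 left out.

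The pipeline was tested on simulated arrays with 200 changed probe sets among 34355, for 24 h against control. It recovered 23.5% of the changed probe sets at 1.5-fold, 38.5% at 2-fold and 56% at 4-fold, with 1, 5 and 5 false calls, and made 0 calls in an unchanged 72 h group. In the data 10960 to 13673 probe sets passed against the control. With so few changed in the simulation the adjustment was stricter, so its recovery and false calls do not describe the real comparisons. A first criterion, recovery of over 75% at 4-fold, was not met, with 112 of 200 recovered. It was then replaced, after these values were seen, by a recovery that rises with the fold and under 10% false calls. Shared controls were weighed with 20 simulations of unchanged groups. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plots drawn with matplotlib 3.10.9.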

Results

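The data were signals from 10 Affymetrix rice arrays hybridised with RNA of seedlings of the cultivar Zhonghua 10, 2 arrays for each of 5 groups. The control seedlings grew with sufficient phosphate, and the other groups were taken after 6, 24, 48 and 72 h in low phosphate. The labels call the 2 samples of a group biological replicates and give no harvest time for the control. No group with sufficient phosphate is given for 6, 24, 48 or 72 h. Seedling age and time of day therefore cannot be told apart from low phosphate in any comparison with the control. Each array carried 57381 probe sets with a median signal between 47.4 and 69.2, and the 72 h arrays had the highest medians, 69.2 and 68.4. Log2 signals of arrays of the same group correlated across probe sets with r between 0.947 and 0.969 over 5 pairs, and arrays of different groups with r between 0.885 and 0.942 over 40 pairs. The number of arrays, 2 per group, limited the precision of every value, and changes below are log2 differences of group means ± SE with n = 2 arrays per group. Where alternatives that ended or made a call are given, the alternatives not named there left it on the same side of 0.05. This leaves out the replicate block and fry, which are given with the other dependences on processing. For fry only the number of list calls is given. For a named gene with both arrays of the dimmer group under a signal of 23.9, the level of the filter, the change is given as at least the difference from that level, a limit chosen after the values were seen, and such changes have no order among the others.

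The 3′ over 5′ signal of control transcripts differed between the groups. At 72 h the log2 ratio of rice actin was 6.10 ± 1.07 (SD, n = 2) against 2.04 ± 0.03 in the control, and that of Gapdh was 5.10 ± 0.53 against 1.75 ± 0.20. Bacterial transcripts measured on the same arrays moved with them at 72 h, dap from 2.097 ± 0.04 to 6.03 ± 0.53 and lys from 1.64 ± 0.01 to 2.74 ± 0.21. The median change of the 4 bacterial transcripts was 0.81 at 6 h, -0.01 at 24 h, 0.08 at 48 h and 2.52 at 72 h. Over the 3 rice genes the median change was 0.71, -0.26, 0.35 and 3.35 at these times. The 4 hybridisation controls, which are added already labelled, had median changes of 0.02, -0.21, -0.02 and -0.06. Control transcripts under a mean control signal of 100 at either end were left out, a limit chosen after their values were seen.

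**Figure D1:**
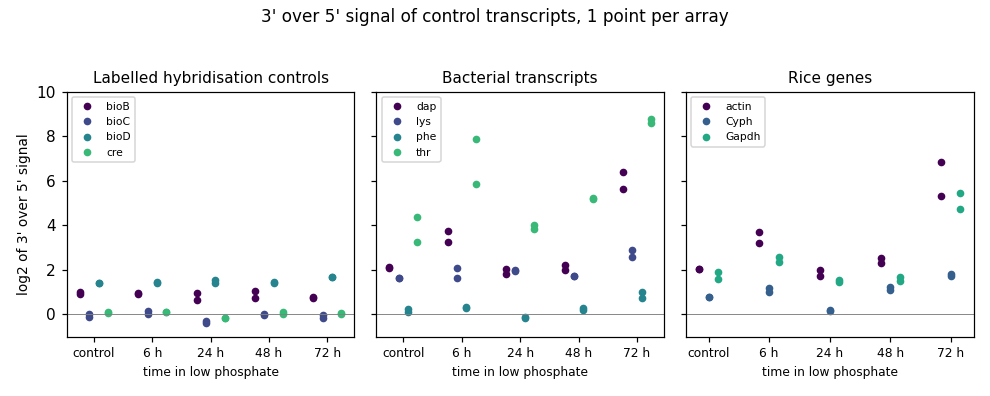
Log2 of the 3′ over the 5′ signal (vertical axis) of control transcripts in the 5 groups (horizontal axis, control and hours in low phosphate), 1 point per array. The ratios of thr, dap, actin and Gapdh were highest at 72 h, while the ratios of bioB, bioC, bioD and cre changed by at most 0.29 in size in their group means from the control mean.

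The phosphate-starvation markers that passed rose by 0.26 to 1.78 in these seedlings. OsSPX1, an SPX-domain sensor that is a standard marker of phosphate starvation, rose by 0.47 ± 0.12 at 24 h (adjusted p = 0.00732), 0.52 ± 0.12 at 48 h (adjusted p = 0.00526) and 0.34 ± 0.12 at 72 h (adjusted p = 0.0418), and at 6 h its change of 0.18 ± 0.12 did not pass. OsSPX2 rose by 0.72 ± 0.23 at 24 h (adjusted p = 0.0253) and 0.77 ± 0.23 at 48 h (adjusted p = 0.0228), with changes of 0.48 at 6 h and 0.49 at 72 h that did not pass. The phosphate transporter OsPht1;2 rose by 0.26 ± 0.08 at 6 h (adjusted p = 0.0294) and 0.58 ± 0.08 at 72 h (adjusted p = 1.84e-04), from control signals of 4674 and 4215 to 6525 and 6697 at 72 h. OsSPX5 rose by 1.78 ± 0.63 at 72 h (adjusted p = 0.0417) from control signals of 24.3 and 20.2, and OsPht1;6 did not pass at any time. Of the 5 measured core phosphate-starvation markers, 1 rose at 6 h, 2 at 24 h, 2 at 48 h and 3 at 72 h, and none fell. The counts adjusted over the list alone were the same. The list as fixed also named OsIPS1, OsIPS2, OsSPX3, OsSPX6, OsPAP10a, OsSQD2, OsGDPD2 and OsPECP. None of these is among the measured members, since only 6 genes of the list were matched on the array. The counts and the list test therefore leave these markers unexamined. The camera test of this list gave adjusted p = 0.394, 0.641, 0.477 and 0.308 at the 4 times, and it did not separate these genes from the others. The rises of OsSPX1 at 48 h and OsPht1;2 at 72 h passed under every alternative that was run, and the other marker calls ended under some. The OsSPX1 rise at 24 h ended without control replicate 2 (adjusted p = 0.0575) or low Pi 24 h replicate 2 (0.0731). Its 72 h rise ended without control replicate 1 (0.0697) or 2 (0.189), low Pi 72 h replicate 1 (0.157) or 2 (0.0899) and either low Pi 48 h array (0.06 each), as well as without the filter on low values (0.0592), with median centring (0.0535) and without an intensity trend (0.117). OsSPX2 at 24 h ended without control replicate 2 (0.235), low Pi 24 h replicate 1 (0.211) or an intensity trend (0.0999) and in a fit of only the 2 groups compared (0.0503). At 48 h it ended without control replicate 2 (0.209), low Pi 48 h replicate 1 (0.0803) or 2 (0.111) or a trend (0.0992), and with quantile normalization (0.0909) or median centring (0.0792). Without control replicate 1 OsSPX2 passed at 6 h (0.0354) and 72 h (0.0328), and OsPht1;6 passed at all 4 times, at 0.00441, 0.0136, 0.0385 and 0.0323. The OsPht1;2 rise at 6 h ended without control replicate 2 (0.213), low Pi 6 h replicate 1 (0.103) or 2 (0.114) or a trend (0.145), and with median centring (0.0983). At 24 h its change of -0.20 ± 0.08 passed as a fall without low Pi 24 h replicate 2 (0.028) and with median centring (0.043). OsSPX5 at 72 h ended without control replicate 1 (0.0816) or 2 (0.124), low Pi 72 h replicate 1 (0.214) or 2 (0.0552), low Pi 48 h replicate 1 (0.0581) or 2 (0.0623) and low Pi 6 h replicate 1 (0.0552) or 2 (0.0577), without the filter (0.0652), with quantile normalization (0.126) and in a fit of only the 2 groups (0.0668).

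Other phosphate genes changed in both directions. Among transporters, OsPht1;4 rose by 1.33 ± 0.10 (adjusted p = 7.87e-07) and OsPht1;8 by 0.68 ± 0.13 (adjusted p = 0.00132) at 6 h, and OsPHO1;2, which loads phosphate into the xylem, rose by 1.11 ± 0.06 at 24 h (adjusted p = 3.96e-08) and 0.45 ± 0.06 at 72 h. A second probe set of OsPHO1;2 gave -0.03 at 24 h and did not pass. OsPht1;8 also rose by 0.54 ± 0.13 at 48 h and 0.37 ± 0.13 at 72 h. OsPht1;1 fell by 0.24 ± 0.06 at 6 h, fell by 0.56 ± 0.06 at 48 h and fell by 0.47 ± 0.06 at 72 h. OsPht1;3, OsPht1;11 and OsPHO1;3 did not pass at any time, although OsPHO1;3 passed at 72 h without an intensity trend (adjusted p = 0.0458). Of the 9 measured phosphate transporters, 3 rose and 1 fell at 6 h, 1 rose at 24 h, 1 rose and 1 fell at 48 h, and 3 rose and 1 fell at 72 h, with the same counts adjusted over the list alone and camera adjusted p of 0.477, 0.863, 0.554 and 0.729. The list's mean and median differed in sign at 24 h (0.30 and -0.08) and at 48 h (-0.23 and 0.04). The regulator OsPHR3 fell by 1.75 ± 0.10 at 6 h (adjusted p = 9.50e-08), fell by 0.52 ± 0.10 at 24 h and fell by 0.39 ± 0.10 at 48 h. OsPHR2, a MYB factor that activates phosphate-starvation genes, fell by 0.62 ± 0.06 at 6 h and rose by 0.19 ± 0.06 at 24 h, 0.43 ± 0.06 at 48 h and 0.39 ± 0.06 at 72 h, where another of its probe sets fell by 0.37. OsPHR1 rose at 6, 24 and 72 h by 0.22, 0.55 and 0.35, each ± 0.08. The SPX protein OsSPX4 fell by 0.50 ± 0.07 at 6 h, fell by 0.33 ± 0.07 at 24 h and rose by 0.26 ± 0.07 at 72 h, and its second probe set did not pass at any of these times. The 3 measured phosphate-response regulators gave 1 rise and 2 falls at 6 h, 2 rises and 1 fall at 24 h, 1 and 1 at 48 h (2 and 1 adjusted over the list alone) and 2 rises at 72 h. Of the 4 measured SPX-domain proteins, 1 fell at 6 h, 2 rose and 1 fell at 24 h, 2 rose at 48 h and 3 rose at 72 h. Adjusted over the list alone, the remaining counts of these lists were the same. OsSPX1, OsSPX2 and OsSPX5 are core markers already counted above, so only OsSPX4 is new here. The transporters likewise include the core markers OsPht1;2 and OsPht1;6.

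Several of these calls rested on single arrays or settings as well. The OsPht1;1 fall at 6 h ended without control replicate 2 (adjusted p = 0.0725), low Pi 6 h replicate 2 (0.0678) or an intensity trend (0.0546). OsPHR1 at 6 h ended without control replicate 1 (0.143) or 2 (0.0968), low Pi 6 h replicate 1 (0.234) or 2 (0.0564), low Pi 48 h replicate 1 (0.0544) or 2 (0.0548), the filter (0.0674) or the trend (0.074), and with quantile normalization (0.0822), median centring (0.153) or only the 2 groups (0.0607). OsPHR2 at 24 h ended without control replicate 1 (0.131), low Pi 24 h replicate 1 (0.0906) or the trend (0.0799), and with median centring (0.0761) or only the 2 groups (0.0795). OsPHR3 at 48 h ended without control replicate 1 (0.11), low Pi 48 h replicate 1 (0.0983) or the trend (0.0744). OsPht1;8 at 48 h ended without control replicate 2 (0.0786), low Pi 48 h replicate 2 (0.0603) or the trend (0.0653) and with median centring (0.0554). At 72 h it ended without control replicate 2 (0.263), low Pi 72 h replicate 2 (0.25), either low Pi 24 h array (0.0528 each), low Pi 48 h replicate 1 (0.0588) or 2 (0.0591), the filter (0.0587) or the trend (0.146), and with median centring (0.0594). OsPHR1 at 48 h (0.20 ± 0.08) passed with the filter at the 60th percentile (0.046).

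**Figure D2:**
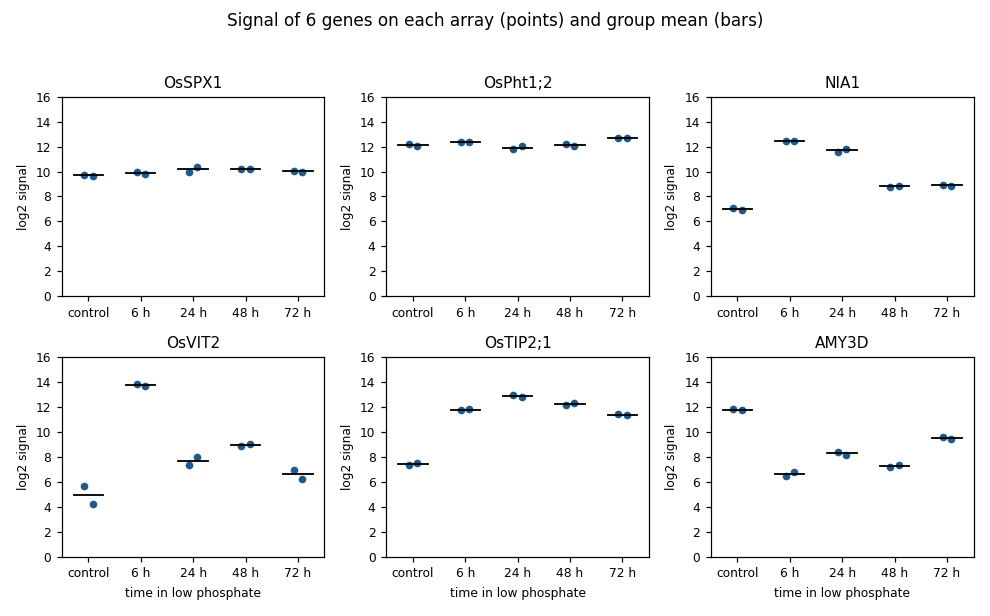
Log2 signal (vertical axis) of 6 genes in the control and at 6, 24, 48 and 72 h in low phosphate (horizontal axis), with points for the 2 arrays of a group and bars for their mean. The group means of OsSPX1 and OsPht1;2 moved by at most 0.58 from the control mean, while the OsVIT2 mean was 8.81 higher at 6 h and AMY3D was lower than the control on every low-phosphate array.

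The 6 h comparison asked which transcripts differed from the control early in low phosphate. OsVIT2 (LOC4346978), a vacuolar iron transporter, rose by 8.81 ± 0.38 (adjusted p = 8.39e-09), from control signals of 51.7 and 19.2 to 14553 and 13648. The nitrate reductase NIA1 rose by 5.49 ± 0.10, and the peroxidase PRX74 and the expansin OsEXPA1 rose by at least 4.38 and 2.60 from control means of 6.8 and 3.2. A second probe set of NIA1 gave -0.03 and did not pass. The lipid transfer protein LTP110-A rose by 4.43 ± 0.18, the tonoplast aquaporin OsTIP2;1 by 4.36 ± 0.08, the mitotic cyclin CYCB1-1 by 4.02 ± 0.90 and the replication helicase subunit OsMCM4 by at least 1.59. Among falls, the alpha-amylase AMY3D (LOC4345814) fell by 5.16 ± 0.14 (adjusted p = 2.71e-10), and OsKS10 changed by -4.11 ± 0.60 and the dehydrin RAB21 by -3.86 ± 0.37. OsMADS5 was lower by at least 3.68, the chitinase OsChia4a by at least 3.27, the initiation factor eIF-4G by at least 2.096, the kinase OsCIPK20 by at least 1.31 and DAPB2 by at least 1.01. In OsVIT2, CYCB1-1, OsKS10 and RAB21, 1 of the 2 arrays of the dimmer group was under 23.9. Another probe set of RAB21 gave -0.76 and passed. Other probe sets of eIF-4G gave -1.64 (adjusted p = 0.00156), -0.09 and 0.27, the last of which passed as a rise (0.0215), and that of DAPB2 gave 0.65 and passed as a rise (0.00255). The DAPB2 call ended without control replicate 2 (adjusted p = 0.0892) and the OsCIPK20 call without control replicate 1 (0.0536) or low Pi 6 h replicate 2 (0.0602). Both also ended in a fit of only the 2 groups compared (0.0877 and 0.0727).

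Several lists had a camera call at 6 h, and none of these passed with an estimated correlation. Iron homeostasis genes had 6 rises, 2 falls and 2 members that did not pass among 10 measured (6 and 2 adjusted over the list alone), with the nicotianamine synthases OsNAS2 and OsNAS3 up by 2.29 ± 0.05 and 2.17 ± 0.05 and the aminotransferase OsNAAT1 by 2.05 ± 0.04. Its camera call (adjusted p = 0.02) had adjusted p = 0.204 with an estimated correlation. Nitrogen uptake and assimilation genes had 7 rises and 2 falls among 10 (7 and 2 adjusted over the list alone), with the glutamine synthetase OsGS1;2 up by 2.83 ± 0.06 and the ammonium transporters OsAMT1;1 and OsAMT1;2 by 1.43 ± 0.10 and 1.31 ± 0.10. That call (adjusted p = 0.0295) had adjusted p = 0.226 with an estimated correlation. Of 53 cell wall genes 31 rose and 3 fell (32 and 4 adjusted over the list alone), among them the expansins OsEXPB7 at 3.11 ± 0.09 and OsEXPB18 at no less than 2.18. Their camera result was adjusted p = 0.00169, and adjusted p = 0.204 with an estimated correlation. Aquaporins had 12 rises and 3 falls among 23 (13 and 4 adjusted over the list alone), with OsPIP2;5 at 3.79 ± 0.07 and OsPIP2;4 at 2.93 ± 0.05. The call (adjusted p = 0.0295) had adjusted p = 0.226 with an estimated correlation. Low-oxygen genes had 4 rises among 5 (4 adjusted over the list alone), the haemoglobins OsNSHB2 and OsNSHB1 at 1.98 ± 0.09 and 1.95 ± 0.26 and the alcohol dehydrogenase Adh2 at 1.199 ± 0.05. Other probe sets of OsNSHB1 gave 0.87 and 1.09, and both passed. Here adjusted p was 0.0295, and adjusted p = 0.226 with an estimated correlation.

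Photosynthesis genes had 7 rises and 1 fall among 9 at 6 h (7 and 1 adjusted over the list alone), with PSB28 at 1.27 ± 0.09 and the chlorophyll-binding protein RCABP89 at 0.55 ± 0.04. The test gave adjusted p = 0.0329, and adjusted p = 0.226 with an estimated correlation, and with all probe sets of a gene averaged the call ended (0.0564). Pathogenesis-related genes and chitinases had 8 falls and 2 rises among 11 (8 and 2 adjusted over the list alone), with PBZ1 at -1.46 ± 0.08 from control signals of 25222 and 25620 and OsChia1c at -1.53 ± 0.07. The camera call had adjusted p = 0.0178, and adjusted p = 0.226 with an estimated correlation. Of 6 WRKY factors 5 fell (5 adjusted over the list alone), OsWRKY62 at -2.24 ± 0.18, with camera adjusted p = 0.0462, and adjusted p = 0.241 with an estimated correlation. Seed reserve and germination genes had 3 falls and 1 rise among 7 (5 and 1 adjusted over the list alone), AMY3E at -2.24 ± 0.50 with 1 of the 2 arrays at 6 h under 23.9, with adjusted p = 0.0357, and adjusted p = 0.232 with an estimated correlation. The WRKY call ended without control replicate 2 (adjusted p = 0.0755), without low Pi 6 h replicate 1 (0.0528) and without either low Pi 24 h array (0.0555 and 0.0592). The seed call ended without control replicate 2 (0.0533), without low Pi 24 h replicate 2 (0.0505) and with all probe sets of a gene averaged (0.178).

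At 6 h, 12432 of 34355 probe sets changed in limma, 6534 up and 5898 down, and with each array centred on its median 5649 up and 6641 down. They included 9285 probe sets of 1 gene each, for 8438 genes. The study's own 2-fold rule gave 3257 up and 2651 down, of which 2056 and 1583 also passed limma. Both arrays of one group lay above both of the other in 67.2% of probe sets, where chance gives 33.3%. The median 3′ over 5′ change of the bacterial transcripts was 0.81 at this time.

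At 24 h the named rises included aquaporins and the named falls the clock gene OsPRR1. The plasma membrane aquaporin OsPIP2;5 (LOC4343121) rose by 6.28 ± 0.07 (adjusted p = 4.56e-14), from a mean log2 signal of 6.95 to 13.23, and the sugar transporter OsSWEET2b by 5.74 ± 0.25. OsTIP2;1 rose by 5.47 ± 0.08, PRX74 by at least 3.34, the kinase OsCIPK25 by 5.02 ± 0.26, NIA1 by 4.75 ± 0.10, OsPIP2;4 by 4.54 ± 0.05 and OsAPRL1 by 4.43 ± 0.11. The second probe set of NIA1 gave -0.34 and did not pass. The nuclease OsBBD1 fell by 6.39 ± 0.14, and the clock gene OsPRR1 changed by -5.92 ± 0.16 (adjusted p = 5.99e-11) and the light-regulated LIR1 by -5.58 ± 0.05. In OsPRR1, 1 of the 2 arrays at 24 h was under 23.9. Further falls were those of OsCIPK10 at -4.51 ± 0.11, the catalase CAT-A at -4.23 ± 0.14, OsC3H37 at -3.80 ± 0.10 and the chloroplast thioredoxin OsCDSP32 at -3.73 ± 0.09. OsCAD8C was lower by at least 1.23, and another of its probe sets gave -0.82 (adjusted p = 0.00462). The OsCAD8C call ended in a fit of only the 2 groups compared (adjusted p = 0.0852).

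All 7 measured clock genes passed at 24 h, 6 down and 1 up (6 and 1 adjusted over the list alone). GI fell by 3.602 ± 0.08, OsPRR73 changed by -2.87 ± 0.06 and OsPRR95 by -2.75 ± 0.05, while the dawn gene OsLHY rose by 3.52 ± 0.07. For the clock list camera gave adjusted p = 0.00249, and adjusted p = 0.204 with an estimated correlation. Nitrogen genes again had 7 rises and 2 falls among 10 (7 and 2 adjusted over the list alone), with OsAMT1;2 at 2.98 ± 0.10 and OsAMT1;1 at 2.88 ± 0.10. Their adjusted p was 0.016, and adjusted p = 0.204 with an estimated correlation. Iron genes had 6 rises and 1 fall among 10 (6 and 1 adjusted over the list alone), with OsVIT2 at 2.68 ± 0.38, with 1 control array under 23.9, and OsNAS2 at 2.16 ± 0.05. For them adjusted p was 0.0185, and adjusted p = 0.204 with an estimated correlation. Auxin response genes had 26 rises and 7 falls among 45 (27 and 9 adjusted over the list alone), with the auxin-conjugating OsGH3-8 at 2.61 ± 0.19 and OsARF1 at 2.06 ± 0.08. Camera gave adjusted p = 0.0273, and adjusted p = 0.204 with an estimated correlation, and 0.0525 without low Pi 24 h replicate 2.

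Aquaporins had 12 rises and 5 falls among 23 at 24 h (12 and 5 adjusted over the list alone), among them OsTIP1;2 at 3.26 ± 0.12. The adjusted p was 0.0295, and adjusted p = 0.226 with an estimated correlation. Cell wall genes had 29 rises and 8 falls among 53 (29 and 8 adjusted over the list alone), OsEXLA4 at 3.32 ± 0.59 with 1 control array under 23.9. Camera gave adjusted p = 0.0273, and adjusted p = 0.235 with an estimated correlation. Pathogenesis-related genes had 8 falls and 2 rises among 11 (8 and 2 adjusted over the list alone), OsChia4a at -2.82 ± 0.52 with 1 of the 2 arrays at 24 h under 23.9 and OsChia1c at -1.91 ± 0.07. Their adjusted p was 0.0205, and adjusted p = 0.231 with an estimated correlation. Seed genes had 4 falls among 7 (4 adjusted over the list alone), AMY3D at -3.50 ± 0.14 and amy2A at -1.18 ± 0.12, with adjusted p = 0.0354, and adjusted p = 0.232 with an estimated correlation. The seed call ended without control replicate 2 (adjusted p = 0.0525), without low Pi 24 h replicate 2 (0.0616) and with all probe sets of a gene averaged (0.185). In all, 13673 probe sets changed at 24 h in limma, 7076 up and 6597 down, and with each array centred on its median 6560 up and 6989 down. They included 9897 probe sets of 1 gene each, for 9019 genes. The 2-fold rule gave 3749 up and 3454 down. The bacterial transcripts' median 3′ over 5′ change was -0.01.

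At 48 h the named rises included replication genes and aquaporins. OsTIP2;1 rose by 4.82 ± 0.08, CYCB1-1 by 4.25 ± 0.90, OsPIP2;5 by 4.21 ± 0.07 and OsVIT2 by 3.99 ± 0.38. PRX74 rose by at least 4.17 (adjusted p = 8.08e-09), OsMCM5 by at least 1.88, OsMCM4 by at least 1.58 and the replication protein OsRPA70b by at least 1.40. AMY3D fell by 4.50 ± 0.14, the stress factor OsDREB1B.1 changed by -3.96 ± 0.81 and the isocitrate lyase OsICL (LOC4343441) by -3.75 ± 0.07, and the stress factor DREB1G was lower by at least 1.71. The calmodulin-like CML15 and CML16 stood at -3.01 ± 0.09 and -2.55 ± 0.08, the jasmonate repressor OsTIFY9 at -2.79 ± 0.71 and OsPM19L1 at -2.66 ± 0.23. In CYCB1-1, OsVIT2, OsDREB1B.1 and OsTIFY9, 1 of the 2 arrays of the dimmer group was under 23.9. The OsRPA70b call ended without low Pi 48 h replicate 1 (adjusted p = 0.0631) or replicate 2 (0.063), and that of OsTIFY9 without control replicate 1 (0.0589) or an intensity trend (0.0717).

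Of 19 histone and cell division genes 7 rose and none fell at 48 h (10 rose adjusted over the list alone), and the list had camera adjusted p = 0.0273, and adjusted p = 0.204 with an estimated correlation. Root-preferential genes had 5 rises among 7 (5 adjusted over the list alone), OsAMT1;2 at 1.63 ± 0.10 and the potassium channel OsAKT1 at 0.87 ± 0.14. Their adjusted p was 0.0178, and adjusted p = 0.204 with an estimated correlation. Cell wall genes had 29 rises and 3 falls among 53 (31 and 3 adjusted over the list alone), OsEXPA3 at 3.35 ± 0.16, with adjusted p = 0.00169, and adjusted p = 0.204 with an estimated correlation. Auxin response genes had 23 rises and 3 falls among 45 (23 and 4 adjusted over the list alone), IAA31 at 1.44 ± 0.09 and IAA1 at 1.25 ± 0.05. The adjusted p was 0.022, and adjusted p = 0.204 with an estimated correlation. Iron genes had 6 rises and 3 falls among 10 (6 and 3 adjusted over the list alone), OsNAS3 at 1.97 ± 0.05. For these adjusted p was 0.0308, and adjusted p = 0.226 with an estimated correlation, and 0.0525 without low Pi 24 h replicate 2.

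Jasmonate and wound genes had 15 falls and 4 rises among 30 at 48 h (15 and 4 adjusted over the list alone), with the allene oxide synthase AOS3 at -1.73 ± 0.20. Camera gave adjusted p = 0.0031, and adjusted p = 0.204 with an estimated correlation. Pathogenesis-related genes had 8 falls among 11 (8 adjusted over the list alone), OsChia1c at -1.30 ± 0.07 and OsChia2a at -1.19 ± 0.05. Their adjusted p was 2.85e-04, and adjusted p = 0.204 with an estimated correlation. Of 6 WRKY factors 4 fell (4 adjusted over the list alone), OsWRKY62 at -1.66 ± 0.18 and OsWRKY71 at -1.20 ± 0.07, with adjusted p = 0.0295, and adjusted p = 0.231 with an estimated correlation. Heat shock genes and chaperones had 13 falls and 7 rises among 40 (14 and 9 adjusted over the list alone), the factor OsHsf-21 at -1.55 ± 0.16. Here adjusted p was 0.0295, and adjusted p = 0.204 with an estimated correlation, and the call ended under quantile normalization (0.0527) and with probe sets averaged (0.0771). Seed genes had 3 falls among 7 (5 adjusted over the list alone), with adjusted p = 0.02, and adjusted p = 0.226 with an estimated correlation, and 0.0571 with probe sets averaged. At 48 h 10960 probe sets changed in limma, 6667 up and 4293 down. They included 8226 probe sets of 1 gene each, for 7574 genes. The 2-fold rule gave 2702 up and 2144 down. The median change of all tested probe sets was 0.11, and with each array centred on its median it was -0.07 and 38.2% of calls were rises, against 60.8% as deposited. The bacterial transcripts' median 3′ over 5′ change was 0.08.

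At 72 h PRX74, OsPIP2;5 and OsTIP2;1 were again among the named rises. OsPIP2;5 rose by 4.47 ± 0.07 and OsTIP2;1 by 3.94 ± 0.08, while PRX74 (LOC4339222) rose by at least 3.34 (adjusted p = 1.89e-08), OsEXPB18 by at least 2.02, OsMCM5 by at least 1.73 and OsMCM4 by at least 1.45. CHL9, a subunit of magnesium chelatase, rose by at least 1.66 and OsMCM7 by 3.77 ± 1.23 with 1 control array under 23.9, both at adjusted p = 0.029. Without control replicate 1 these 2 calls ended (adjusted p = 0.187 and 0.158), as they did without low Pi 72 h replicate 1 (0.173 and 0.0826) or replicate 2 (0.0586 and 0.129), without an intensity trend (0.0665 and 0.0817) and with only the 2 groups compared (0.0659 and 0.113). The OsMCM7 call also ended with quantile normalization (0.0508). The 8 named falls were HIRL1, lower by at least 5.59, the ornithine aminotransferase OAT, lower by at least 3.31, the ceramidase OsCDase at -5.57 ± 0.66, CDKF-4 at -5.24 ± 0.94, the potassium transporter OsHAK7 at -4.86 ± 0.18, the kinase OSK3 at -4.58 ± 0.16, the catalase CAT-B at -4.52 ± 0.17 and the phenylalanine ammonia-lyase PAL at -4.45 ± 0.23. Each of these 8 genes had other probe sets, and none of those moved by more than 0.52 in size, while the following passed: CDKF-4 at 0.46 and CAT-B at 0.52 as rises, and CAT-B at -0.23 and -0.18, PAL at -0.35 and -0.25, OAT at -0.43 and HIRL1 at -0.23 as falls. In OsCDase and CDKF-4, 1 of the 2 arrays at 72 h was under 23.9. For HIRL1 they gave -0.23 and 0.02, for OsHAK7 -0.13, for OsCDase -0.04 and for OAT -0.43. These falls stood beside the median 3′ over 5′ change of 2.52 in the bacterial transcripts.

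Root-preferential genes had 6 rises among 7 at 72 h (6 adjusted over the list alone), with the silicon transporter Lsi2 at 0.67 ± 0.05. The list had adjusted p = 0.0135, and adjusted p = 0.204 with an estimated correlation. Of 10 cytokinin type response regulators 9 rose and 1 fell (9 and 1 adjusted over the list alone), OsRR9 at 1.67 ± 0.08 and OsRR2 at 0.84 ± 0.12. The adjusted p was 0.0354, and adjusted p = 0.226 with an estimated correlation, and 0.0505 without low Pi 24 h replicate 2. Cell wall genes had 30 rises and 7 falls among 53 (30 and 8 adjusted over the list alone), OsEXPB7 at 2.91 ± 0.09, with adjusted p = 0.0273, and adjusted p = 0.235 with an estimated correlation. Aquaporins had 11 rises and 3 falls among 23 (11 and 4 adjusted over the list alone), OsPIP2;4 at 2.94 ± 0.05. The aquaporin call had adjusted p = 0.043, and adjusted p = 0.226 with an estimated correlation, and the call ended without low Pi 24 h replicate 1 (0.0572) or replicate 2 (0.06).

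Jasmonate and wound genes had 15 falls and 3 rises among 30 at 72 h (15 and 3 adjusted over the list alone), with the reductases OsOPR5 at -1.89 ± 0.11 and OsOPR6 lower by at least 2.71. A second probe set of OsOPR5 gave 0.72 and did not pass. Camera gave adjusted p = 0.00198, and adjusted p = 0.204 with an estimated correlation. Pathogenesis-related genes had 7 falls and 2 rises among 11 (7 and 2 adjusted over the list alone), OsChia1c at -1.97 ± 0.07 and OsChia1a at -1.22 ± 0.05. Here adjusted p was 0.0161, and adjusted p = 0.226 with an estimated correlation. Of 6 WRKY factors 4 fell and 1 rose (4 and 1 adjusted over the list alone), OsWRKY62 at -1.07 ± 0.18 and OsWRKY51 at -0.995 ± 0.09. The WRKY call (adjusted p = 0.0492) had adjusted p = 0.243 with an estimated correlation. It also ended without control replicate 2 (0.0826), without low Pi 72 h replicate 1 (0.0542), without either low Pi 24 h array (0.0572 and 0.06) and without either low Pi 48 h array (0.0536 and 0.0514) and with probe sets averaged (0.0569). At 72 h 13550 probe sets changed in limma, 7515 up and 6035 down. They included 9448 probe sets of 1 gene each, for 8593 genes. The 2-fold rule gave 4692 up and 2937 down, and under quantile normalization 43.6% of its calls were rises, against 61.5% as deposited. The median change of all tested probe sets was 0.16, and 0.06 under quantile normalization.

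The comparison of 72 h with 6 h asked how signals moved between these times, which may also differ in seedling age and time of day. OsVIT2 differed by -7.17 ± 0.38 (adjusted p = 7.12e-08), lower at 72 h, OsCslF2 by -4.31 ± 0.59 and OsCDase by -3.99 ± 0.66, and HIRL1 and OsWNK2 were lower by at least 3.66 and 2.47. Other probe sets of OsWNK2 and OsCDase gave 0.15 and 0.07, and those of HIRL1 gave -0.06 and 0.44, the latter passing as a rise (adjusted p = 0.00504). RAB21 was higher at 72 h by 3.28 ± 0.37, and another of its probe sets by 0.90. OsMADS5 was higher by at least 3.44, OsCIPK20 by at least 1.56, DAPB2 by at least 1.13 and eIF-4G by at least 0.76. Other probe sets of eIF-4G gave -2.50 and -0.55, both passing the opposite way (adjusted p = 7.51e-05 and 2.20e-04), and 0.56, and that of DAPB2 gave -0.28. In OsCslF2, OsCDase and RAB21, 1 of the 2 arrays of the dimmer group was under 23.9. The DAPB2 and OsCIPK20 calls ended without low Pi 72 h replicate 1 (adjusted p = 0.0571 and 0.0537) and with only the 2 groups compared (0.0654 and 0.0526), as did the eIF-4G call in the latter fit (0.138). Iron genes had 8 falls among 10 (8 falls and 1 rise adjusted over the list alone), OsNAS2 at -1.17 ± 0.05 and OsIRT2 at -1.70 ± 0.30. Camera gave adjusted p = 0.00102, and adjusted p = 0.204 with an estimated correlation. Nitrogen genes had 7 falls among 10 (7 falls and 1 rise adjusted over the list alone), NIA1 at -3.57 ± 0.10 and OsAMT1;1 at -1.57 ± 0.10, and the second NIA1 probe set gave -2.25 (adjusted p = 0.0504). The test gave adjusted p = 0.0042, and adjusted p = 0.204 with an estimated correlation. Photosynthesis genes had 7 falls and 1 rise among 9 (7 and 1 adjusted over the list alone), RCABP69 at -1.38 ± 0.05, with adjusted p = 0.00198, and adjusted p = 0.204 with an estimated correlation. Seed genes had 5 rises and 1 fall among 7 (5 and 1 adjusted over the list alone), AMY3D at 2.89 ± 0.14. The seed call (adjusted p = 0.0462) had adjusted p = 0.235 with an estimated correlation, and it ended without control replicate 2 (0.0525), low Pi 72 h replicate 2 (0.0501) or either low Pi 24 h array (0.0581 and 0.06), with quantile normalization (0.0522) and with probe sets averaged (0.221). In limma 12056 probe sets differed between 72 h and 6 h, 5997 higher and 6059 lower, and with each array centred on its median 6504 higher and 5616 lower. The bacterial transcripts' median 3′ over 5′ change from the control was 0.81 at 6 h and 2.52 at 72 h.

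Over the 5 groups together, 21078 of 34355 probe sets changed in limma's F-test. PRX74, OsTIP2;1 and OsPIP2;5 were among 2009 probe sets that rose at all 4 times, and 1449 fell at all 4. Independent lists of these sizes would share 57.1 and 24.9. In 20 simulations with no effect in any group, the control included, 0.05 and 0 were shared. In these simulations at most 0.15 probe sets on average were called the same way at 2 times. They therefore cannot show how many shared calls the control pair gives where many probe sets pass. The 4 comparisons used the same 2 control arrays, too few to split, so part of the excess may come from them. Changes at 2 times correlated across probe sets, which are not independent replicates, with r between 0.428 and 0.609, against 0.498 to 0.503 in the simulations. Their covariance was between 0.415 and 0.522, against 0.119 to 0.121 simulated.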

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

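The comparison of 72 h with 6 h and the tests of 5′ loss and of the authors' scaling were set beforehand, and the tests of degraded seedling RNA, of scaling fall by fall and of rises were chosen after their results were seen.

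Phosphate genes whose effect differed between 72 h and 6 h, by limma's test of that difference with adjusted p under 0.05, moved both ways. OsPHR3 differed by 1.53 (from -1.75 at 6 h to -0.22 at 72 h), OsPHR2 by 1.01, OsSPX4 by 0.76, OsPHO1;2 by 0.40 and OsPht1;2 by 0.31. OsPht1;4 differed by -1.19 (from 1.33 to 0.14) and OsPht1;1 by -0.23. The OsPht1;2 difference missed the threshold without low Pi 6 h replicate 1 (adjusted p = 0.0612) or 2 (0.0553), without low Pi 72 h replicate 2 (0.0671) and without an intensity trend (0.0903), with a range of 8.42e-04 to 0.0903 over its alternatives. That of OsPht1;1 missed it without low Pi 6 h replicate 1 (0.0897) and without a trend (0.0664), with a range of 0.00736 to 0.0897. A second OsPHO1;2 probe set gave 0.05 and did not pass.

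The lists of nitrogen uptake and assimilation, iron homeostasis and photosynthesis differed by -0.81, -1.30 and -0.52 on average between 72 h and 6 h, and the seed reserve list by 1.25. The nitrogen and iron means lean on NIA1 and OsVIT2, the largest of the named differences in each list. Of the 7 nitrogen members lower at 72 h, those named by the rule were NIA1 at -3.57, OsAMT1;1 at -1.57, OsGS1;1 at -1.23 and OsGS1;2 at -1.03. Of the 8 iron members lower, the rule named OsIRT2 at -1.70, OsNAS2 at -1.17 and OsNAS3 at -1.04, beside OsVIT2 at -7.17, which went from 8.81 at 6 h to 1.63 at 72 h. Of 7 photosynthesis genes lower, RCABP69 differed by -1.38, RCABP89 by -1.07, CAB2R by -0.73 and PSB28 by -0.65. Of 5 seed genes higher, the differences were 2.89 for AMY3D, 2.02 for AMY3E and 0.99 for amy2A. The AMY3E difference missed the threshold without low Pi 6 h replicate 1 (adjusted p = 0.0552) or low Pi 72 h replicate 1 (0.0543), with a range of 0.00366 to 0.0552 over its alternatives. The seed list missed it without control replicate 2 (0.0525), low Pi 24 h replicate 1 (0.0581) or 2 (0.06) or low Pi 72 h replicate 2 (0.0501), with quantile normalization (0.0522) and with probe sets averaged (0.221), with a range of 0.0268 to 0.221.

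Named genes outside these lists with a fitted difference were HIRL1 at -5.07, OsCslF2 at -4.31, OsCDase at -3.99 and OsWNK2 at -3.69, lower at 72 h. OsMADS5 at 3.995, DAPB2 at 3.62, OsCIPK20 at 3.51, RAB21 at 3.28 and eIF-4G at 3.22 were higher. For HIRL1, OsWNK2, OsMADS5, DAPB2, OsCIPK20 and eIF-4G both arrays of the dimmer group were under a signal of 23.9, so these hold as at least 3.66, 2.47, 3.44, 1.13, 1.56 and 0.76 in size. Those of DAPB2 and OsCIPK20 missed the threshold without low Pi 72 h replicate 1 (adjusted p = 0.0571 and 0.0537), with ranges of 0.00547 to 0.0654 and 0.0013 to 0.0537 over their alternatives. With only the 2 groups compared both missed it too (0.0654 and 0.0526), as did eIF-4G (0.138, range 2.18e-04 to 0.138). Other probe sets of these genes are given above with the comparison.

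A signal outside the gene comparisons came from the control probe sets, whose bacterial spike-in transcripts gained 2.52 in median log2 3′ over 5′ ratio from control to 72 h.

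Falls of over 2 log2 units at 72 h were weighed beside that gain, and among 2522 genes with several tested probe sets, 155 of the 220 with such a fall (70.5%) had another probe set that did not fall, against 37 of 92 (40.2%) at 24 h (two-sided Fisher's exact test, p = 9.36e-07), 50 of 87 (57.5%) at 6 h and 11 of 18 (61.1%) at 48 h, when the spike-in ratio had moved by 0.08. Among rises of over 2 log2 units, 41 of 71 (57.7%) at 72 h had another probe set that did not rise, against 37 of 91 (40.7%) at 24 h (two-sided Fisher's exact test, p = 0.0394). The share was 50.8% at 6 h and 52.5% at 48 h. For 72 h against 6 h it was 82.1% among rises and 68.4% among falls, so the disagreement is not particular to falls. A probe set counted as not fallen, or not risen, unless it moved that way with adjusted p under 0.05. A fall that missed this threshold thus counted as not fallen, and a small fall that passed counted as fallen. These Fisher tests count genes, which share the same arrays and control pair and can appear at both times. Their p-values therefore do not measure the spread between arrays. Degradation within the seedlings as the whole cause is argued against by the 2.52, since bacterial transcripts were not in the plants, provided the spike-ins were added before labelling, which the labels do not state. Scaling by the authors as the cause needed fewer such falls after quantile normalization. Their number went from 816 to 1226, a rise the bound set beforehand had not foreseen, and 100% of the 816 stayed falls. The median change of all tested probe sets at 72 h was 0.16, so normalization could hardly lessen falls of this size and the 100% adds little. A median above 0 argues against a scaling common to all probe sets as the cause, unless most probe sets had shifted together. A loss of 5′ signal during labelling is a candidate explanation for part of these falls, and an effect of 72 h in low phosphate on the same genes stays open and untested.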

How the results depend on the processing

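Most alternatives were planned, and the tests without the 6 h or 72 h arrays in the fit and with 1 probe set per gene were chosen after the data had been seen. Counts of changed probe sets and of list calls stayed within 1.5 times of the reported value in 155 of their alternatives and moved further in 23. For list shifts 1693 alternatives kept direction and side of the threshold, 73 lost a call, 19 gained one and 3 reversed. Fry was tallied there only for lists with a camera call, so the calls that fry added are not among the 19. For named genes the numbers in the same order were 5103, 144, 20 and 0. With 1 array left out, where the lone array was assumed to vary like the other groups, counts ranged from 9842 to 12951 at 6 h, 11614 to 13815 at 24 h, 7837 to 11624 at 48 h, 11068 to 14273 at 72 h, 9367 to 12729 for 72 h against 6 h, 19506 to 21019 in the F-test and 29 to 40 for list calls. The 2-fold rule then ranged over 6735 to 6987, 8186 to 8521, 5392 to 6063 and 8133 to 8413 at the 4 times, each above the 5908, 7203, 4846 and 7629 with all arrays, and the F-test stayed below its 21078, and the cause was not tested. Without the 72 h arrays in the fit limma called 12685 at 6 h, without the 6 h arrays 13076 at 72 h, and without both pairs 13358 at 24 h, 10607 at 48 h and 16725 in the F-test of the 3 groups left. With 1 probe set per gene, fewer were tested, and 8762, 9267, 8058 and 8723 changed at the 4 times and 7965 between 72 h and 6 h. With no filter, so with more probe sets, the 2-fold rule gave 16478, 18195, 15139 and 20101, and above the 60th percentile 2866, 3907, 2093 and 3082. The balance of its calls turned in some of these. At 48 h it gave 6613 up and 8526 down with no filter, against 2702 and 2144 as reported. At 72 h it gave 1338 up and 1744 down above the 60th percentile, against 4692 and 2937 as reported. With 32 added to the means it gave 3099, 4265, 2143 and 4127, with each treated array beyond each control array 2994, 3957, 2197 and 3773, and with adjusted p under 0.05 as well 3639 at 6 h, 2604 at 48 h and 4450 at 72 h, stricter by construction. Camera's 38 list calls became 0 with an estimated correlation, 107 with fry, which does not compare a list with other genes, 44 with quantile normalization and 32 with probe sets averaged. Under quantile normalization the photosynthesis list at 48 h turned to a mean of 0.243 (adjusted p = 0.0314, range 0.0314 to 0.771 over its alternatives), and cytosolic ribosomal proteins turned at 48 h to 0.295 (adjusted p = 2.26e-04, range 2.26e-04 to 0.679) and at 72 h to 0.2 (adjusted p = 0.0387, range 0.0387 to 0.99); the cause was not tested. Ranges over a list's alternatives leave out the estimated correlation and fry. At low signal over background the log2 values spread most, so changes of dim probe sets carry the widest errors.

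With the replicate number as a block, the counts were 12274, 13520, 10819 and 13385 at the 4 times, 11853 for 72 h against 6 h and 20825 in the F-test, and 35 lists were called. Replicate numbers did not pair the arrays: over 10 pairs of groups the deviations of same-numbered arrays correlated at r between -0.009 and 0.017 across probe sets, 0 of them over 0.1. Under the block the calls of WRKY factors at 6 h (adjusted p = 0.0501) and 72 h (0.057), of the seed list for 72 h against 6 h (0.0537) and of OsPHR1 at 6 h (0.0532), OsPht1;8 at 72 h (0.0501) and OsSPX1 at 72 h (0.0528) ended, OsSPX2 passed at 6 h (0.0433) and 72 h (0.0388), and no other call given changed.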

Other observations

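The scaling alternatives and list tests used here were planned, and the tests of harvest times, of scaling, of low phosphate, of root tissue and of the control pair were chosen after the results were seen.

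Several gene groups not yet described changed member by member without a camera call for the list, and the members in this and the next paragraph were not run under the alternatives. OsMGD1, a synthase of the galactolipids that replace phospholipids, rose by 0.98 ± 0.08 at 6 h, 1.24 ± 0.08 at 24 h, 0.70 ± 0.08 at 48 h and 0.39 ± 0.08 at 72 h (n = 2 arrays per group), while OsMGD3 stood at -0.57 ± 0.10 at 24 h and rose by 0.27 and 0.35 at 48 and 72 h, and OsMGD2 did not pass. Of 3 class III peroxidases, 3 rose at 6 h, 2 at 24 h and 2 at 48 h, and at 72 h 2 rose and 1 fell, PRX112 at -0.64 ± 0.21. The actin gene ACT1, the only housekeeping gene measured, rose by 1.14, 1.04, 0.76 and 0.77 at the 4 times. Of 7 phosphate-sparing glycolysis and respiration genes, 1, 3, 1 and 1 rose and 3, 2, 4 and 4 fell at the 4 times (1, 3, 1 and 1, and 4, 2, 4 and 4, adjusted over the list alone), with camera adjusted p of 0.362, 0.994, 0.293 and 0.0942. With all probe sets of a gene averaged this list passed at 72 h (0.0285, range 0.0285 to 0.201 over its alternatives). The sucrose synthase OsSUS1 rose by 1.52 ± 0.05 at 6 h and 1.41 ± 0.05 at 48 h, OsSUS4 fell at all 4 times (-0.83, -0.58, -0.39 and -1.06), and the alternative oxidase OsAOX1A rose by 1.46 ± 0.07 at 24 h. Of 25 sulfate, potassium and zinc transporters, 6, 6, 5 and 5 rose and 9, 6, 4 and 6 fell (6, 7, 5 and 5, and 9, 6, 5 and 7, adjusted over the list alone), with camera adjusted p of 0.615, 0.989, 0.796 and 0.449. The potassium transporter OsHAK1 rose by 1.36, 1.24, 1.66 and 0.37, each ± 0.09, and OsHAK13 stood at -3.001 ± 0.61 at 6 h with 1 array under a signal of 23.9. The list's mean was 0.08, 0.09 and 0.17 at 6, 24 and 48 h where camera pointed down, and its median at 24 h was -0.06.

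Of 7 dehydration genes, 2, 4, 1 and 3 rose and 3, 1, 4 and 0 fell at the 4 times, with the same counts adjusted over the list alone and camera adjusted p of 0.641, 0.0874, 0.0529 and 0.38. At 48 h this list passed as a fall without low Pi 6 h replicate 1 (0.049) or 2 (0.048), without low Pi 72 h replicate 1 (0.0444) or 2 (0.0453) and with quantile normalization (0.0319), with a range of 0.0319 to 0.0763 over its alternatives. The dehydrin OsDhn1 rose by 1.31, 2.53, 0.71 and 0.52, each ± 0.08, while OsLEA19 rose by 2.12 ± 0.10 at 24 h and stood at -1.002 ± 0.10 at 48 h. Of 22 phenylpropanoid and flavonoid genes, 8, 3, 5 and 4 rose and 6, 10, 9 and 8 fell, again the same over the list alone, with camera adjusted p of 0.828, 0.177, 0.0654 and 0.235. The laccase LAC19 changed by -2.82, -3.12, -1.37 and -2.47, each ± 0.14, and OsCAD3 rose by 1.96, 1.75, 0.43 and 1.68, each ± 0.10. Of 7 starch synthesis genes, 2, 1, 3 and 2 rose and 0, 1, 0 and 2 fell (1, 1, 4 and 2, and 0, 1, 0 and 2, adjusted over the list alone), with SSII-2 up by 1.27 ± 0.11 at 6 h, SSII-1 up by 1.62 ± 0.10 at 24 h and camera adjusted p of 0.348, 0.641, 0.295 and 0.828. Of 5 glutathione S-transferases, 2, 2, 1 and 1 rose and 2, 3, 4 and 2 fell, the same over the list alone, with GSTZ5 up by 1.07 ± 0.06 at 72 h, GSTU6 at -1.32 ± 0.06 at 24 h and camera adjusted p of 0.994, 0.38, 0.0952 and 0.419. Of 23 cytosolic ribosomal proteins, 13, 14, 7 and 5 rose and 5, 4, 8 and 6 fell (13, 14, 8 and 7, and 5, 4, 8 and 6, adjusted over the list alone), RPS26 by 1.21 ± 0.05 at 6 h, with camera adjusted p of 0.284, 0.0942, 0.552 and 0.688. Quantile normalization made the ribosomal list a call at 6 h (adjusted p = 9.46e-04, range 9.46e-04 to 0.332 over its alternatives) and 24 h (0.00372, range 0.00372 to 0.141). Mean, median or test of a list differed in sign for starch synthesis at 72 h (mean 0.56, median 0.05, test down), histones and cell division at 24 h (mean 0.72, median 0.20, test down), ribosomal proteins at 48 h (mean 0.03, median -0.02, test down) and 72 h (0.06, 0.01, test down), photosynthesis at 48 h (mean 0.03, median -0.01, test down), cytokinin type regulators at 6 h (mean 0.10, test down), the clock list at 72 h (mean -0.53, median 0.01), phenylpropanoids at 72 h (mean 0.02, median -0.11) and phosphate-sparing genes at 24 h (mean -0.02, median -0.05, test up).

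Lists called at some times had no call at others. Quantile normalization made aquaporins a call at 48 h (adjusted p = 0.341 as reported, 0.00372 with it, range 0.00372 to 0.412 over the alternatives). Nitrogen genes at 48 h (0.077) passed without control replicate 2 (0.0463) or low Pi 48 h replicate 2 (0.0454), with a range of 0.0454 to 0.174. Root-preferential genes at 24 h (0.0513) passed with quantile normalization (0.0231), without control replicate 2 (0.0424), low Pi 6 h replicate 1 (0.049) or 2 (0.048) or low Pi 24 h replicate 1 (0.0433), with a range of 0.0231 to 0.0783. Whether these lists differed between the times with and without a call was tested only for 72 h against 6 h.

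Clock genes were lower at 24 h, by a list mean of -2.38, with OsPRR1 and GI down and OsLHY up by 3.52. The median change of all tested probe sets at 24 h was 0.04. This argues against a scaling common to all probe sets as the cause, unless most probe sets had shifted together. The list mean of -2.36 after quantile normalization adds little, since with that median it could hardly have moved. A time of day shared by the 24, 48 and 72 h harvests and other than the control's is argued against by a list mean of 0.285 at 48 h and by 7 of 7 members that differed between 24 h and 48 h by over 2 SE. A 24 h harvest at another time of day than the others cannot be told apart from an effect of 24 h in low phosphate, because the labels give no time of day and no control taken with the 24 h seedlings, and OsLHY at 3.515 is part of the pattern that prompted the question. The list mean of -0.53 at 72 h averages members that moved both ways. At 72 h OsLHY changed by 2.198, OsPRR1 by -1.66, GI by -0.763 and OsPCL1 by -4.064, the last with 1 array under 23.9. OsPRR73 and OsPRR95 rose by 0.379 and 0.18 then, and OsPRR37 stood at 0.011. At 6 h OsLHY, OsPRR1 and OsPCL1 changed by 1.455, -1.77 and -2.473. Part of the pattern was therefore not confined to 24 h. This does not decide between these explanations, because the labels give no control taken with the 6 or 72 h seedlings either. Both stay open and untested.

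Root-preferential genes as a list were called higher at 48 and 72 h, with 5 and 6 of 7 members up and none down. Of the members, OsTIP2;1, OsPIP2;5 and Lsi1 are also in the aquaporin list and OsAMT1;2 in the nitrogen list. The results of these lists are therefore not separate evidence. At 6 h (camera adjusted p = 0.302) and 24 h (0.0513) there was no call, and no time passed with an estimated correlation. The missing call at 24 h does not make this a late rise. The rises of OsPIP2;5, OsTIP2;1, OsAMT1;2 and OsAKT1 were largest at 24 h, at 6.28, 5.47, 2.98 and 1.19, while Lsi2 did not pass and Lsi1 fell then. OsTIP2;1 and OsPIP2;5 carried the means, so that at 72 h the mean was 1.39 and the median 0.552, and Lsi2 stood at -0.59 ± 0.05 and OsCASP1 at -1.16 ± 0.29 at 6 h and Lsi1 at -1.26 ± 0.05 at 24 h. More root tissue in the 48 and 72 h samples cannot be told apart from a response of these genes, because the root share of each gene's signal was not measured and no member fell at these times. A control pair that stands apart cannot be told apart from it either, since all 4 comparisons use the same 2 control arrays, and the 2009 probe sets that rose at all 4 times fit either. A response to low phosphate stays open and untested.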
